A study of Mus musculus with 18 samples.

How the data were processed

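Gene expression was measured on 18 Affymetrix MOE 430 2.0 mouse arrays, each holding RNA of sorted skin cells of 1 K5tTA x pTRE-H2B-GFP mouse (FvB and CD1 parents). Per the labels' protocols, doxycycline at 1 g per kg of food stopped H2B-GFP synthesis from PD18 to PD21 or from PD22 to PD25, so that cells lost the label 2-fold at each division. Per the design text, cells were sorted on CD34, α6-integrin and GFP, and 5 ng of RNA per fraction was amplified with Ovation chemistry before labelling and hybridisation. Titles give the chase, the fraction and a mouse number of 1 to 3, and these labels define the 6 groups of 3 arrays. The sex of the mice, the dates of hybridisation and the sorting gates in numbers are not given in the sources used here.

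The deposited values are probe set intensity signals on a linear scale, which GCOS made with present calls per the submitters' processing notes and the design text, and the GCOS version is not given in the sources used here. Every array's 2% trimmed mean was 500, so the authors' values were already scaled between arrays, and no further normalisation was applied. The present calls were not used here. Array medians lay between 60.3 and 116.6. For arrays, the number of mice limits the precision, and GCOS signals of dim probe sets are noisy, so fold changes on the log2(signal + 16) scale understate the change of dim genes.

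The table held 45101 probe sets, of which 64 were controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed. Symbols were checked through Entrez identifiers against a RefSeq gene table, which matched 34741 of the 1-symbol probe sets and changed 0 symbols. Probe sets with several or no symbols were left out, and 18193 genes were represented. A probe set was kept when it exceeded the median of its array in at least 3 of the 18 arrays, and the probe set with the highest mean stood for its gene, which left 11569 genes. Ccnb1, Cdkn1c and Shh, named in advance, had no tested probe set and were not analysed here.

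The group means of all 18 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with 12 residual and 11.2 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over 11569 genes within a comparison, and a gene passed at 0.05. The comparisons were bulge against non-bulge at each age, divided against undivided bulge at each age, PD25 against PD21 in each fraction, and the differences between the ages of the division effect and of the bulge effect. Each bulge fraction against non-bulge at each age was added after the data were seen. Errors of fold changes are standard errors of the fit, with 3 mice per group, and the bulge mean takes both bulge fractions of the 3 mice.

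In all, 29 gene lists were fixed. They cover bulge stem cells, basal interfollicular epidermis, epidermal differentiation, isthmus and infundibulum, sebaceous gland, hair germ, hair shaft, DNA replication, mitosis and cell cycle inhibitors. Pathway lists cover Wnt, Hedgehog, BMP and TGF-beta, FGF and MAPK, Notch, matrix and adhesion, dissociation and immediate early genes, ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol synthesis and the interferon response. Lists for other cell types the sort could hold were melanocyte, dermal fibroblast, endothelial, immune, muscle, Merkel and nerve, and erythroid, some with few tested genes. Some genes stand in several lists, so list calls are not independent. The bulge list shares Lgr5, Dkk3, Sfrp1, Wif1, Fzd7 and Tcf7l1 with the Wnt list and Npnt, Postn, Itga6 and Col17a1 with the matrix list. It shares Bmp6 and Id2 with the BMP list, Fgf18 with the FGF list and Gas1 with the Hedgehog list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 29 lists of a comparison. For fits with the mouse or run as a block, or without an array, lists were tested with limma's cameraPR on the moderated t values, also at 0.01. Those list values differ from the main ones in the statistic as well as in the fit, so a changed call cannot be assigned to the fit alone. List counts are given over all genes and adjusted over the list alone. The groups, comparisons, lists, alternatives and the rule for named genes were set before the data were examined, apart from the comparisons named above as added. The fits with array run as a block and within each run, described below, were also added after the data were seen. That rule took, per comparison, the 10 largest increases and 10 largest decreases among genes that passed, had no overlap between the arrays compared and had a higher group mean above the median of group means. It added up to 4 members that passed from each list that was called or had 3 or more such members, and it always took a fixed set of marker and cell cycle genes. Where fewer than 10 genes passed, all were named, and where none passed, the 5 with the lowest unadjusted p were given as values.

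The mouse numbers pair the fractions of a chase because the labels give them to the same animal. As a check, the residuals of arrays of the same mouse correlated at 0.075 to 0.462 over 18 pairs, 17 of them over 0.1, with a median of 0.198. Arrays of different mice in the same array run had a median of 0.0645 over 12 pairs. The main fit has no mouse term, so its counts and standard errors do not use the pairing of fractions by mouse. A fit with the mouse as a block is an alternative, under which the count between bulge and non-bulge at PD21 was 830. Between ages, where mouse is nested in age, the mouse was a random block (duplicateCorrelation through statmod 1.5.0, correlation 0.231).

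The hybridisation control BioB split the arrays into 9 at 926.5 to 1520.3 (run A) and 9 at 3063 to 4504 (run B), and the second principal component, with 13.7% of the variance, separated the same arrays. The labels do not name these runs. Each PD21 group held 2 arrays of run A and 1 of run B, and each PD25 group held 1 of run A and 2 of run B, so run was added as a block, and every comparison was also fitted within each run with the spread pooled over groups. No pair of arrays shared more than 0.324% of identical values. The 3' to 5' signal ratio was 0.91 to 1.23 for Actb probe sets and 3.1 to 11.6 for those of Gapdh.

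Other alternatives were pseudocounts of 1 and 64, quantile normalisation, no filter, a stricter filter at the 75th percentile, the mean of a gene's probe sets, no variance trend, array weights, only the groups compared, a fold change of at least 2, and leaving out each array in turn. Other splits of the same arrays were counted, all of them or 100 drawn with a fixed seed. The procedure was tested on simulated data for divided against undivided bulge at PD25 over 11569 genes. The simulated noise was independent between genes and between arrays, without the run and mouse shifts of the real arrays. The rates that follow therefore need not hold for the real arrays. Of 50 genes changed at each size the procedure recovered 13 at 2-fold, 30 at 4-fold, 46 at 8-fold and 50 at 16-fold. It made 7 false calls among 146, and 0 calls with limma when nothing was changed. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.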

Results

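The series profiled epithelial cells sorted from mouse skin by their division history. The mice carried a keratin 5-driven histone H2B-GFP label that doxycycline switches off, after which each division dilutes the label 2-fold. Cells were collected at postnatal day (PD) 21 after doxycycline from PD18, or at PD25 after doxycycline from PD22, ages that the design text ties to different hair cycle phases. Surface CD34 and α6-integrin separated the bulge, the niche of hair follicle stem cells, from non-bulge cells. Retained GFP separated bulge cells with 0 divisions (undivided) from bulge cells with 1 to 2 divisions (divided). Each of the 6 groups held 3 arrays, 1 per mouse, and the 3 fractions of an age came from the same 3 mice. The 18 arrays had the same trimmed mean signal of 500 and fell into 2 runs of 9 arrays each (runs A and B), so counts within each run stand beside the pooled ones.

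Bulge cells at PD21 differed from non-bulge cells in genes that included Lhx2, Sox9, Dkk3, Sfrp1 and Grem1. Lhx2, a LIM homeobox factor of hair follicle stem cells, was higher in the bulge by 3.03 ± 0.22 (log2 fold change ± SE, 3 mice), Sox9 by 1.98 ± 0.23, Runx1 by 1.65 ± 0.23 and the R-spondin receptor Lgr5 by 2.51 ± 0.47. The lowest of 6 Runx1 probe sets had the opposite sign, at -0.51. The secreted Wnt modulators Dkk3 and Sfrp1 were higher by 3.48 ± 0.37 and 3.16 ± 0.27, the BMP antagonist Grem1 by 3.43 ± 0.31 and the growth factor binding protein Igfbp5 by 4.81 ± 0.60. Ripply3, Phldb2 and the transcription factor Sox6 were lower, at -2.83 ± 0.48, -2.79 ± 0.47 and -2.37 ± 0.45, and so was the BMP receptor Bmpr1b at -1.99 ± 0.46. Cd34 was higher by 6.31 ± 0.40, which follows from the sort. Itga6, Krt15, Krt5 and Krt14 did not pass the test, with Krt15 at 0.36 ± 0.47 (adjusted p = 0.82). In mice 1 to 3 Krt15 stood at 15.29, 15.333 and 14.238 on the log2 scale in non-bulge cells. Its values were 16.219, 15.804 and 14.407 in undivided and 15.699, 15.389 and 14.346 in divided bulge. Krt15 was thus higher in the bulge of each mouse, and the fit without a mouse term counts the spread between mice as error. In limma, 489 of 11569 genes passed, 322 higher and 167 lower in the bulge. The count was 335 within run A, 118 within run B and 830 with the mouse as a block, and it fell to 307 without non-bulge mouse 1 and to 240 without non-bulge mouse 2.

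The list of bulge stem cell genes, which holds both sorting markers, had a median of 1.36 at PD21 (camera adjusted p = 3.07e-26). Of its 30 measured members 16 were higher and 1, the interleukin 1 decoy receptor Il1r2, was lower, or 24 and 1 adjusted over the list alone. Of 27 Wnt pathway genes 8 were higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 0.00325, and adjusted p = 0.199 with an estimated correlation), with the receptor Fzd2 at 2.72 ± 0.30. Lgr5, Dkk3 and Sfrp1, which were among the higher Wnt genes, also stand in the bulge list. Of 27 BMP and TGF-beta genes 7 were higher and 4 lower (10 and 4 adjusted over the list alone; adjusted p = 0.00176, and adjusted p = 0.0615 with an estimated correlation). Id4, an inhibitor of differentiation, stood at 3.33 ± 0.38 and the latent TGF-beta binding protein Ltbp1 at 2.79 ± 0.37, while the other probe set of Ltbp1 stood at -0.40. Among 18 FGF and MAPK genes 4 were higher, Fgf1 by 2.67 ± 0.49 and Fgfr1 by 2.35 ± 0.29 among them, and 5 were higher and 1 lower adjusted over the list alone (adjusted p = 0.0306). The FGF list had an adjusted p = 0.212 with an estimated correlation. Among 27 matrix and adhesion genes 4 were higher (9 adjusted over the list alone), with the collagen Col4a4 at 2.80 ± 0.54 and the integrin Itgb8 at 1.65 ± 0.38 (adjusted p = 0.00053, and adjusted p = 0.0844 with an estimated correlation). Of 9 measured dermal fibroblast and papilla genes 3 were higher over all genes and over the list alone (adjusted p = 0.025, and adjusted p = 0.2 with an estimated correlation). These were the matrix genes Col1a1 at 3.82 ± 0.48, Col6a1 at 2.08 ± 0.50 and Sparc at 1.56 ± 0.31. With the mouse as a block and cameraPR, epidermal differentiation (median 0.33, camera adjusted p = 0.245) reached 0.0307. Sebaceous gland (median -0.43, camera adjusted p = 0.15) and mitosis (median -0.26, camera adjusted p = 0.0817) both reached 0.0336.

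At PD25 the same contrast held more genes, and the rise lay in the divided bulge. Against non-bulge cells, in comparisons added after the data were seen, divided bulge differed in 21 genes at PD21 and 1026 at PD25. Undivided bulge differed in 1278 and 1220. The bulge mean at PD21 thus averages unlike fractions. Lhx2 was higher in the bulge by 4.35 ± 0.22, Sox9 by 2.72 ± 0.23, Runx1 by 2.14 ± 0.23 and Lgr5 by 3.12 ± 0.47. The transcription factor Nfatc1 was higher by 1.94 ± 0.29, after 0.91 ± 0.29 at PD21 (adjusted p = 0.085), and that difference between the ages did not pass (1.03 ± 0.41, adjusted p = 0.62). The adaptor Sorbs2 (5.91 ± 0.41) and Igfbp5 (5.38 ± 0.60) were among the 10 largest increases named, and Grem1 (4.48 ± 0.31), Dkk3 (4.20 ± 0.37) and Fzd2 (4.02 ± 0.30) were higher as well. Ligands and receptors higher in non-bulge cells included the EGF family member Epgn at -4.38 ± 0.46, Il1r2 at -4.35 ± 0.42, the alarmin Il33 at -4.12 ± 0.38, Wnt3 at -3.78 ± 0.45 and Bmp4 at -3.77 ± 0.42. The Wnt target Axin2 was lower in the bulge at -1.38 ± 0.24, and Cd34, a sorting marker, was higher by 7.25 ± 0.40. In limma 1424 genes passed, 814 higher and 610 lower, with 691 within run A and 1155 within run B. For the difference of the bulge effect between the ages, 0 genes passed in limma, against 757 with an unadjusted p under 0.05. The count was 8 within run A, 0 within run B and 30 with the mouse as a block. Its lowest unadjusted p belonged to Ly6d, Fgfbp1, Fcgbp, Pm20d1 and Mtus1, with differences of -1.96, -1.80, -2.56, 3.63 and 1.42 and adjusted p-values of 0.065 to 0.076.

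At PD25, 23 of the 30 bulge genes were higher and 1 lower (25 and 1 adjusted over the list alone; median 2.08, adjusted p = 3.4e-23). Hedgehog pathway genes were higher as a list (median 0.97, 4 of 10 higher, 6 adjusted over the list alone, adjusted p = 0.000955), among them the co-receptor Boc at 1.55 ± 0.29 and the transcription factor Gli3 at 1.40 ± 0.27. Of 27 matrix and adhesion genes 10 were higher (12 adjusted over the list alone), including Itgb8 at 2.89 ± 0.38 and Col4a4 at 2.81 ± 0.54 (adjusted p = 2.54e-05). These 3 lists held with an estimated correlation, at adjusted p-values of 0.006, 0.029 and 0.0339. Of the BMP and TGF-beta genes 11 were higher and 5 lower over all genes and over the list alone (adjusted p = 0.00526, and adjusted p = 0.0624 with an estimated correlation). Ltbp1 stood at 4.35 ± 0.37 and Smad7 at 3.66 ± 0.68. FGF and MAPK genes had 6 higher and 2 lower over all genes and over the list alone (adjusted p = 0.0429, and adjusted p = 0.265 with an estimated correlation). Lists lower in the bulge were the interferon response (median -0.73, 3 of 12 lower, 4 adjusted over the list alone, adjusted p = 0.0274) and basal interfollicular epidermis (median -0.27, 3 of 12 lower, 5 adjusted over the list alone, adjusted p = 0.0171). The immunoproteasome subunit Psmb8 was lower at -1.91 ± 0.33, Ly6d at -2.89 ± 0.24 and Gata3 at -1.44 ± 0.26. Both lost the call at adjusted p = 0.0899 and adjusted p = 0.0624 with an estimated correlation. Immediate early genes, which cell dissociation induces, were lower by a median of -0.41 (1 higher and 6 lower of 25, 2 and 6 adjusted over the list alone, adjusted p = 0.0276, and adjusted p = 0.389 with an estimated correlation). Fos was lower at -2.10 ± 0.45 and Fosb at -2.17 ± 0.50. Ribosome biogenesis and Myc genes had a median of -0.43 with 2 of 25 lower over all genes and over the list alone (adjusted p = 0.000759, and adjusted p = 0.089 with an estimated correlation). Wnt genes went both ways. They were called by cameraPR with the mouse as a block (adjusted p = 0.000133) but not by camera without it (adjusted p = 0.156). Glycolysis genes did likewise (median -0.28, adjusted p = 0.0343 by cameraPR and 0.131 by camera).

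**Figure D1:**
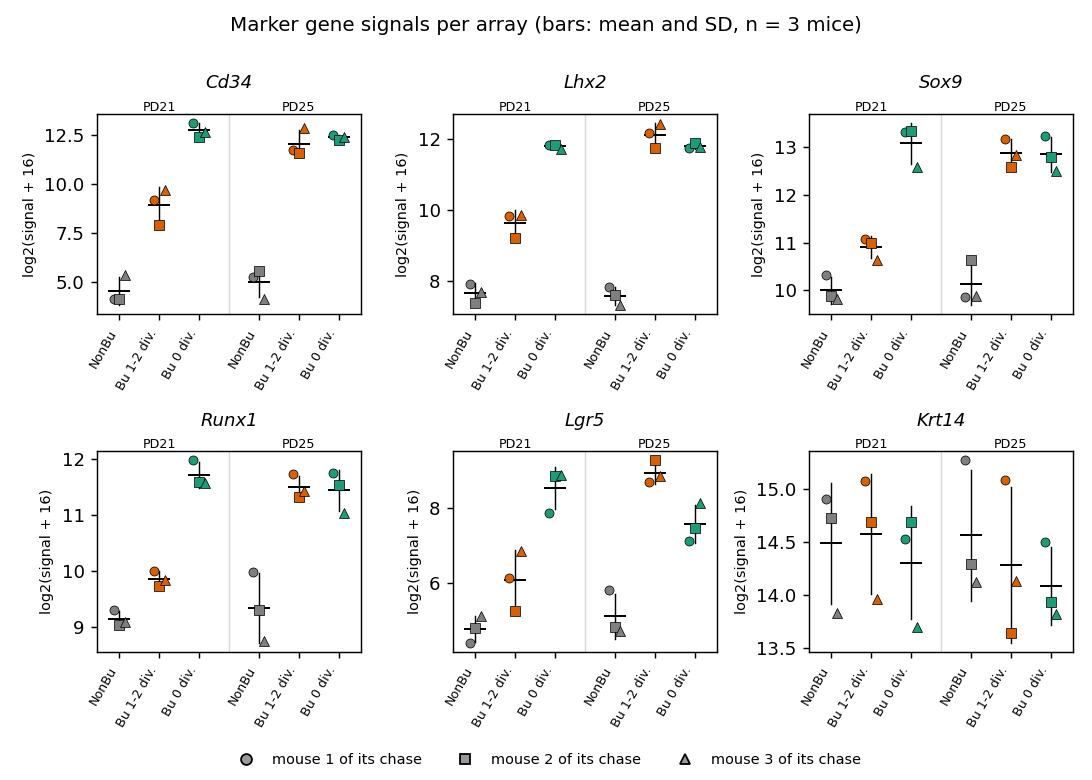
Signals of Cd34, Lhx2, Sox9, Runx1, Lgr5 and Krt14 as log2(signal + 16) on each of the 18 arrays, by fraction and age, with symbols for the mouse and bars for the mean and SD of 3 mice. Lhx2 of the divided bulge lies between non-bulge and undivided bulge at PD21 (means 7.68, 9.64 and 11.80) and beside the undivided bulge at PD25 (12.10 against 11.79).

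Divided and undivided bulge cells were compared within each age to relate division history to expression. At PD21, the divided fraction had lower levels of the bulge transcripts. A mixture with 93.5, 93 and 81% non-bulge cells in mice 1 to 3 left 0 of 578 genes deviating. A change in the divided cells and non-bulge cells in their gate could therefore not be told apart. Lhx2 of the divided fraction was lower at -2.16 ± 0.25 (log2 fold change ± SE, 3 mice), Sox9 at -2.17 ± 0.27, Runx1 at -1.86 ± 0.27, Lgr5 at -2.44 ± 0.54 and Dkk3 at -2.87 ± 0.43. Igfbp5 and the retinoic acid binding protein Crabp1 showed the largest decreases named, at -5.32 ± 0.70 and -5.00 ± 0.67. The transporter Slc16a9 (4.59 ± 0.75), Il33 (3.96 ± 0.44), Bmp4 (3.52 ± 0.49), Il1r2 (3.41 ± 0.49) and Wnt3 (3.36 ± 0.52) were higher in divided cells. Cd34, the transcript of a sorting marker, averaged 12.73 ± 0.36 (SD, n = 3) in undivided, 8.93 ± 0.92 in divided and 4.52 ± 0.73 in non-bulge cells on the log2 scale, a difference of -3.80 ± 0.46 between the bulge fractions. Krt15, Itga6, Krt5 and Krt14 did not pass. In limma 958 genes passed, 452 higher and 506 lower in divided cells, with 803 within run A, 94 within run B, where each group has 1 array, and 1533 with the mouse as a block.

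Of the 30 bulge genes 18 were lower in divided cells at PD21 and 1, Il1r2, was higher (23 and 1 adjusted over the list alone; median -1.89, adjusted p = 1.06e-18). The Hedgehog list had 4 of 10 lower (5 adjusted over the list alone; median -1.02, adjusted p = 0.000862), with Boc at -1.85 ± 0.34 and the growth arrest gene Gas1 at -1.56 ± 0.31. Of the BMP and TGF-beta genes 9 were lower and 4 higher (11 and 4 adjusted over the list alone; adjusted p = 0.00141), with Grem1 at -2.85 ± 0.36 and Bmp4 in the opposite direction. Of the matrix genes 6 were lower (8 adjusted over the list alone; adjusted p = 5.12e-05), with Itgb6 at -2.36 ± 0.41 and Lamb1 at -1.64 ± 0.30. Interferon response genes were higher (median 1.08, 3 of 12, 5 adjusted over the list alone, adjusted p = 0.000927), with Psmb8 at 2.16 ± 0.38 and the ISG15 protease Usp18 at 2.10 ± 0.59. With an estimated correlation these 5 lists held at adjusted p-values of 0.0149 for the bulge, 0.0306 for Hedgehog and 0.0325 for the other lists. The mitosis list was higher in divided cells (median 0.89, 6 of 31 higher, 15 adjusted over the list alone, adjusted p = 2.93e-07) but had an adjusted p = 0.371 with an estimated correlation. The kinesin Cenpe was higher by 1.59 ± 0.40 and the anaphase activator Cdc20 by 1.41 ± 0.44. Mean levels of the mitosis list in non-bulge, divided and undivided cells were -0.097, 0.127 and -0.863. Those of the interferon list were 0.428, 0.536 and -0.51, so the divided fraction lay near non-bulge cells in both. FGF and MAPK genes were lower (5 of 18, 9 lower and 1 higher adjusted over the list alone, adjusted p = 0.000677, and adjusted p = 0.0541 with an estimated correlation), with Fgf1 at -3.11 ± 0.56. Sebaceous genes were higher (4 of 12, 5 adjusted over the list alone, adjusted p = 0.00969, and adjusted p = 0.25 with an estimated correlation). The adipogenic receptor Pparg stood at 2.55 ± 0.69 and the acyl-CoA synthetase Acsbg1 at 2.15 ± 0.40. With the mouse as a block and cameraPR, DNA replication (median 0.32, camera adjusted p = 0.0855) reached 0.0458. Epidermal differentiation (median 0.45, camera adjusted p = 0.132) reached 0.0315 and the Wnt list (median -0.09, camera adjusted p = 0.261) 0.00592. The dermal markers moved apart, with Col6a1 and Sparc lower at -3.15 ± 0.58 and -1.64 ± 0.35 and Col3a1 higher by 2.77 ± 0.65.

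Set against non-bulge cells separately, a comparison added after the data were seen, the undivided bulge at PD21 differed in 1278 genes (708 higher, 570 lower; 1028 within run A, 409 within run B, 1926 with the mouse as a block). The divided bulge differed in 21, all higher (7 within run A, 12 within run B, 49 with the mouse as a block). Those 21 included Cd34 at 4.41, the collagen Col1a1 at 3.55, the proteoglycan Cspg4 at 3.00, Lhx2 at 1.96, the T-box factor Tbx1 at 1.91 and Sfrp1 at 1.83. Each of the 21 was also higher in undivided bulge than in non-bulge cells at PD25. The count for the divided bulge depended on the variance model and on single arrays, with 4 genes without the variance trend, 1 when only the groups compared were fitted and 4 to 30 when an array was left out.

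At PD25 few or no genes separated the bulge fractions, 0 without and 10 with the mouse as a block. Lhx2 differed by 0.32 ± 0.25, Sox9 by 0.02 ± 0.27, Runx1 by 0.05 ± 0.27 and Cd34 by -0.33 ± 0.46 between divided and undivided cells. Other bulge genes moved without passing. Lgr5 was higher in divided cells, as its difference between the ages (3.80) exceeded its PD21 decrease (-2.44). In mice 1 to 3 Igfbp5 stood at 11.56, 11.552 and 11.605 in undivided and 8.871, 9.635 and 10.711 in divided cells. Crabp1 stood at 11.116, 10.806 and 10.065 and at 8.078, 8.91 and 8.548. The values of lowest unadjusted p were those of Ntn4, a netrin, at 2.14 ± 0.36 (adjusted p = 0.052), the protease Prss23 at 1.51 ± 0.27 (0.052) and the serotonin transporter Slc6a4 at 1.54 ± 0.29 (0.099). Next came Itih5 at 2.36 ± 0.46 (adjusted p = 0.1) and the LDL receptor family member Lrp4 at 1.22 ± 0.25 (0.12). In limma 0 genes passed, against 635 with an unadjusted p under 0.05, and 10 passed with the mouse as a block, 23 within run A, 0 within run B and 16 with array weights. As lists, DNA replication genes were lower in divided cells (median -0.69, run A -1.07, run B -0.54, adjusted p = 2.49e-16, and adjusted p = 0.128 with an estimated correlation) and so were mitosis genes (median -0.50, run A -1.33, run B -0.23, adjusted p = 1.96e-08), although 0 members passed in limma. The mitosis call was lost at adjusted p = 0.609 with an estimated correlation, and by cameraPR without divided mouse 1 (adjusted p = 0.0568). The list means of divided minus undivided cells in mice 1 to 3 were -1.02, -0.102 and -1.004 for replication and -1.25, 0.23 and -0.66 for mitosis. The array of divided mouse 1 stood apart, with the highest Gapdh 3' to 5' ratio (11.6), the lowest array weight (0.527) and the highest score on principal component 3 (55.4). The topoisomerase gene Top2a differed by -0.69 ± 0.30 (adjusted p = 0.83), short of the test. Cholesterol synthesis genes were lower (median -0.36, adjusted p = 3.78e-05, and adjusted p = 0.128 with an estimated correlation). Matrix genes were higher (median 0.21, 0 over all genes in limma and 2 adjusted over the list alone, adjusted p = 0.0084, and adjusted p = 0.29 with an estimated correlation). With the mouse as a block and cameraPR, isthmus and infundibulum genes (median 0.42, camera adjusted p = 0.0853) reached 0.00938. Epidermal differentiation (median 0.21, camera adjusted p = 0.358) reached 0.0383 and sebaceous gland (median -0.34, camera adjusted p = 0.0853) 0.0355.

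The division effect itself differed between the ages in 137 genes, 94 with a higher value at PD25 and 43 with a lower one. Sex-linked genes also set the PD21 arrays apart from the PD25 arrays (below), so age and sex cannot be told apart here. Non-bulge cells in the divided gate at PD21 could also underlie such differences and stay open. Lgr5 differed by 3.80 ± 0.76, Cd34 by 3.47 ± 0.65, Fzd2 by 2.95 ± 0.50, Sfrp1 by 2.62 ± 0.45, Lhx2 by 2.47 ± 0.35, Sox9 by 2.19 ± 0.38 and Runx1 by 1.92 ± 0.38. Each of these was lower in divided cells at PD21. Il33 (-3.27 ± 0.62), the apoptosis regulator Pmaip1 (-3.87 ± 0.75), and the spindle genes Prc1 (-2.65 ± 0.62) and Kif11 (-1.98 ± 0.45) differed the other way. Bulge genes (median 1.64, 8 of 30 past the test, 19 adjusted over the list alone) and matrix genes (median 0.96) were called with an estimated correlation as well, both at an adjusted p of 0.0119. The count was 56 within run A, 0 within run B and 506 with the mouse as a block. It was 69 without PD21 divided mouse 2 and 251 without PD25 divided mouse 2, the lowest and highest when an array was left out.

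**Figure D2:**
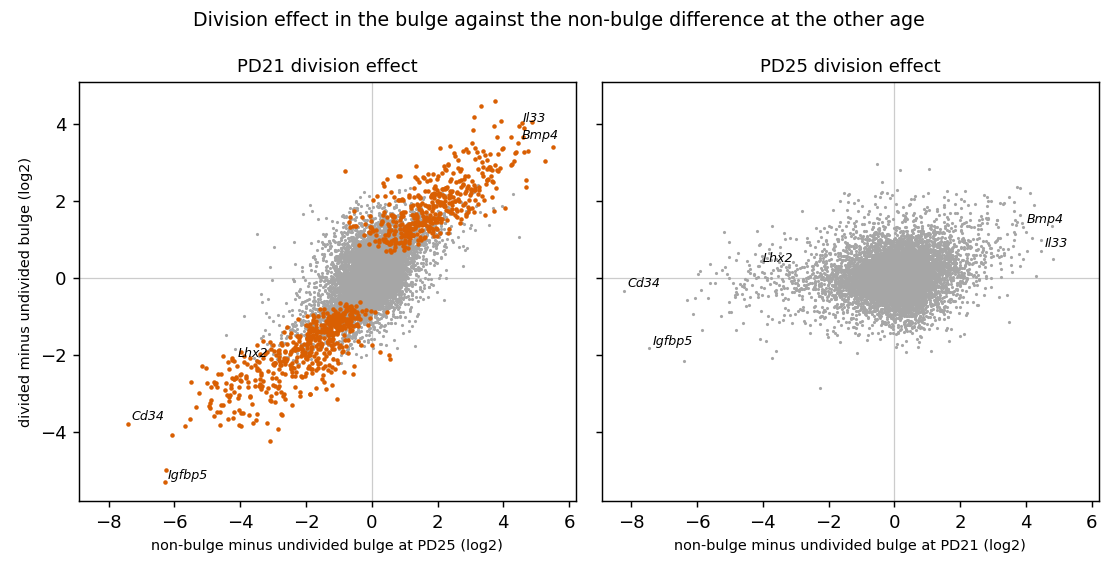
Log2 fold change between divided and undivided bulge for 11569 genes (vertical) against that between non-bulge and undivided bulge at the other age (horizontal, no arrays shared), with genes that passed the vertical comparison in orange. At PD21 the values rise together (r = 0.732 across genes), and at PD25 they spread around 0 (r = 0.181) with 0 genes past the test.

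PD25 was compared with PD21 in each fraction to follow the change of hair cycle phase. All 3 comparisons carry sex-linked genes. The Y-linked Eif2s3y was higher at PD25 by 6.79 in undivided, 6.61 in divided and 7.25 in non-bulge cells, and Xist was lower at -8.28, -8.33 and -9.28, with the 9 PD25 arrays apart from the 9 PD21 arrays. Undivided bulge cells differed in 11 genes, 7 higher and 4 lower at PD25 (9 and 8 after quantile normalisation). The kinetochore gene Spc25 (1.74 ± 0.34), the kinesin Kif11 (1.73 ± 0.32), the exonuclease Eri2 (1.67 ± 0.30) and the fatty acid elongase Elovl6 (1.42 ± 0.28) were higher at PD25. Fcgbp (-2.69 ± 0.40), Lrp4 (-1.57 ± 0.25) and Cyp4b1 (-1.20 ± 0.23) were lower. The other genes were Eif2s3y, Kdm5d, Uty and Xist, and Top2a stayed short of the test at 1.33 ± 0.30 (adjusted p = 0.07). The count was 34 within run A, 6 within run B, 22 with the mouse as a random block and 41 with run as a block, 6 without PD25 undivided mouse 1 and 25 without PD21 undivided mouse 2. Spc25, Kif11, Eri2 and Elovl6 were not called without the variance trend or with the mean of a gene's probe sets, and the lowest of 3 Elovl6 probe sets stood at -0.33.

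As lists, mitosis genes were higher in undivided cells at PD25 (median 1.47, run A 1.36, run B 1.74, adjusted p = 2.24e-31, and adjusted p = 0.0735 with an estimated correlation). Of 31 members 1 passed over all genes and 28 adjusted over the list alone. Their mean relative to all arrays was -0.86 ± 0.36 (SD, n = 3) at PD21 and 0.64 ± 0.14 at PD25. DNA replication genes had a median of 0.96 (adjusted p = 2.27e-17, and adjusted p = 0.0735 with an estimated correlation), with 0 of 30 past the test over all genes and 17 adjusted over the list alone. Cholesterol synthesis genes (median 0.58, adjusted p = 0.00013) and sebaceous genes (median 0.56, adjusted p = 0.000742) were also higher. Cholesterol had an adjusted p = 0.0735 and sebaceous an adjusted p = 0.0964 with an estimated correlation. Muscle genes, 3 in all, had a median of 0.54 (adjusted p = 0.00845, and adjusted p = 0.153 with an estimated correlation). Lists lower at PD25 were isthmus and infundibulum (median -0.60, adjusted p = 0.00132, and adjusted p = 0.158 with an estimated correlation) and epidermal differentiation (-0.53, 0.000909, and adjusted p = 0.353 with an estimated correlation). So were cell cycle inhibitors (-0.43, 0.0243, and adjusted p = 0.158 with an estimated correlation). Matrix genes (-0.37, 0.000836, and adjusted p = 0.0803 with an estimated correlation) and immediate early genes (-0.34, 0.00154, and adjusted p = 0.158 with an estimated correlation) were lower as well. The same held for bulge genes (-0.32, 0.00107, and adjusted p = 0.194 with an estimated correlation) and basal epidermis genes (-0.25, 0.00845, and adjusted p = 0.0735 with an estimated correlation). BMP and TGF-beta genes (median -0.21, adjusted p = 0.0491, and adjusted p = 0.158 with an estimated correlation) lost the call with the mouse as a block and cameraPR at adjusted p = 0.054. Epidermal differentiation had a median of -0.96 within run A and 0.27 within run B.

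Divided bulge cells differed in 907 genes between the ages, 505 higher and 402 lower at PD25. Because the PD21 divided fraction also fits a mixture with mostly non-bulge cells, a change in the divided cells and a change in the make-up of their gate cannot be told apart. Bulge transcripts were higher at PD25, with Tbx1 at 3.03 ± 0.37, Lgr5 at 2.84 ± 0.54, Lhx2 at 2.47 ± 0.25, Sox9 at 1.96 ± 0.27, Runx1 at 1.65 ± 0.27 and Nfatc1 at 1.46 ± 0.34. The ligand Wnt5b (4.39 ± 0.47) and the proteoglycan Bgn (4.37 ± 0.45) were higher too. Il33 (-3.66 ± 0.44), Wnt3 (-3.60 ± 0.52), Bmpr1b (-3.41 ± 0.53) and the immediate early gene Fosb (-3.03 ± 0.58) were lower. Of the bulge genes 13 were higher and 1 lower (18 and 1 adjusted over the list alone; median 1.37, adjusted p = 1.96e-11, and adjusted p = 0.084 with an estimated correlation). Matrix genes had 5 higher (7 adjusted over the list alone; median 0.40, adjusted p = 0.00052, and adjusted p = 0.084 with an estimated correlation). Interferon (median -1.01, 3 lower, 4 adjusted over the list alone, adjusted p = 0.00413, and adjusted p = 0.084 with an estimated correlation) and epidermal differentiation genes (-0.72, 1 higher and 4 lower, 1 and 5 adjusted over the list alone, 0.00213, and adjusted p = 0.644 with an estimated correlation) were lower. Immediate early (-0.67, 1 higher and 5 lower, 1 and 7 adjusted over the list alone, 0.00122, and adjusted p = 0.223 with an estimated correlation) and basal epidermis genes (-0.27, 2 lower, 3 adjusted over the list alone, 0.0219, and adjusted p = 0.0907 with an estimated correlation) were also lower. The count was 595 within run A and 59 within run B, and 532, 525 and 548 without PD21 divided mouse 1, PD21 divided mouse 2 and PD25 divided mouse 3.

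Non-bulge cells differed in 5 genes between the ages: Eif2s3y, Kdm5d, Uty, Xist and the X-linked Bex1, which was lower at PD25 at -4.90 ± 0.72 (7 genes within run A, 5 within run B). Ribosome biogenesis and Myc genes were higher (median 0.36, adjusted p = 8.56e-06, and adjusted p = 0.118 with an estimated correlation). Hedgehog genes (median -0.33, adjusted p = 0.0484, and adjusted p = 0.173 with an estimated correlation) and cell cycle inhibitors (median -0.21, adjusted p = 0.0484, and adjusted p = 0.285 with an estimated correlation) were lower. Lhx2, Sox9, Runx1, Krt5 and Krt14 did not pass, with values of -0.09, 0.13, 0.20, 0.11 and 0.08.

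**Figure D3:**
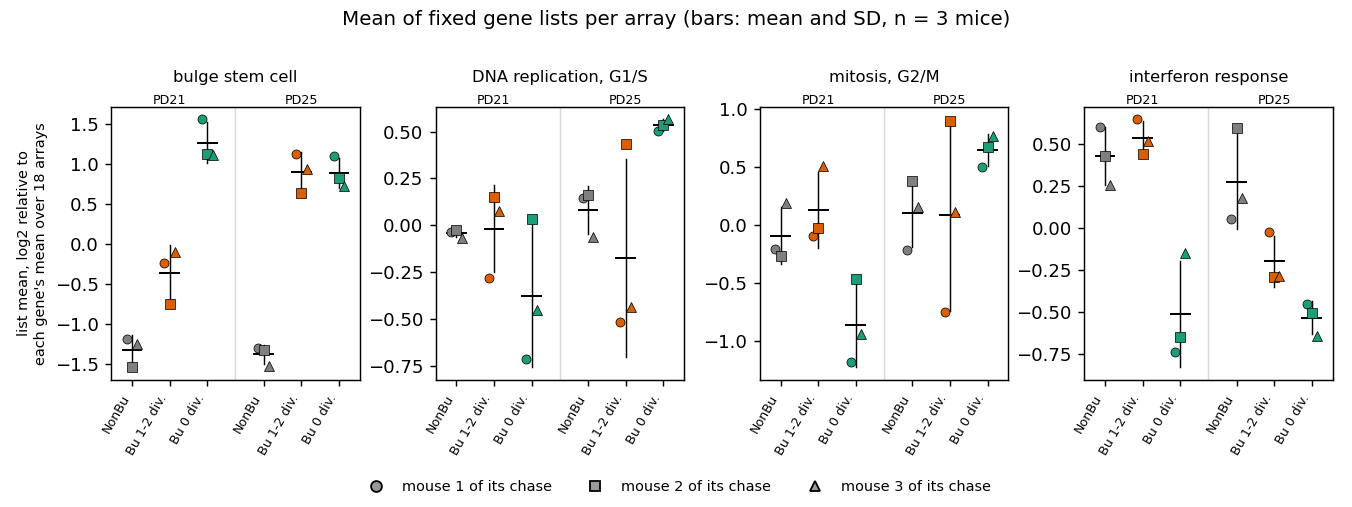
Mean log2 level of the bulge, DNA replication, mitosis and interferon lists on each array, relative to each gene's mean over 18 arrays, with bars for the mean and SD of 3 mice. The mitosis mean of undivided bulge is -0.86 at PD21 and 0.64 at PD25, and the divided bulge arrays at PD25 spread from -0.75 to 0.89.

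**Figure D4:**
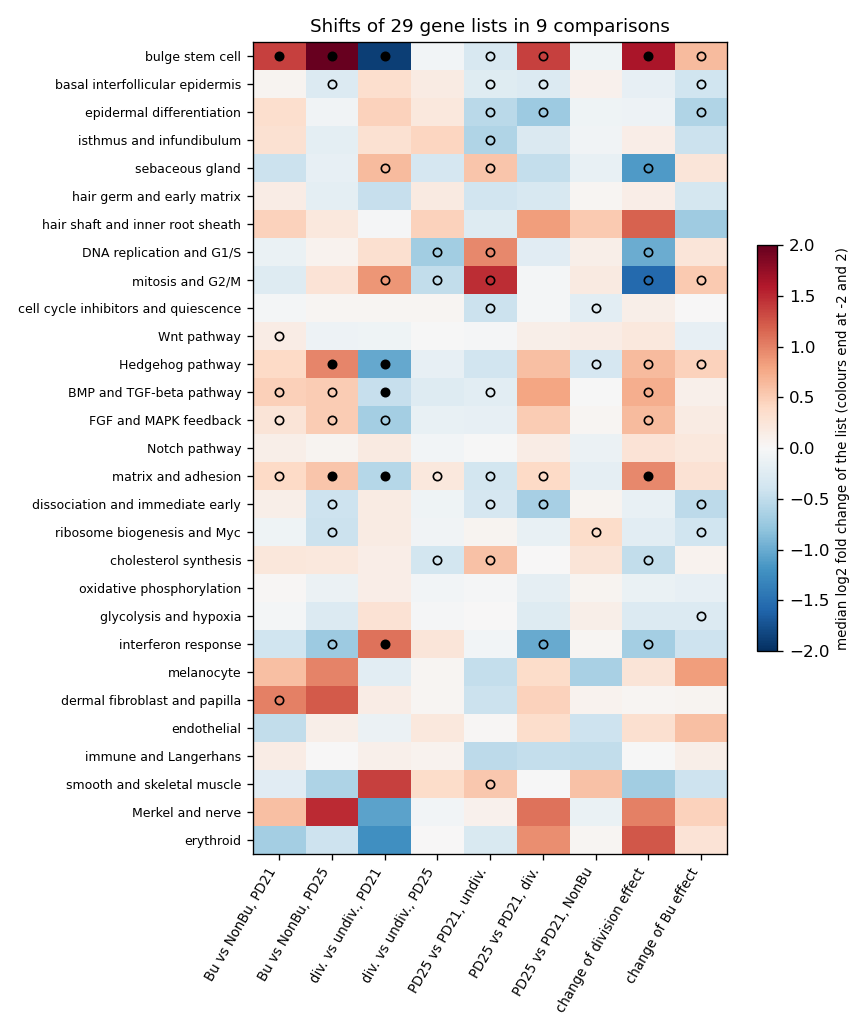
Median log2 fold change of each of 29 lists in 9 comparisons, as colour, with open circles for lists called by camera and filled circles for those also called with an estimated correlation. In all, 67 of the list and comparison pairs carry a circle, and 11 of these circles are filled.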

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

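The tests of the swapped fractions, of the array run at PD21 and of sex, and the forced shares of the mixture, were chosen only after the results were seen. The division effect differed between the ages in 137 genes, with Lgr5 at 3.80, Cd34 at 3.47, Lhx2 at 2.47, Sox9 at 2.19 and Runx1 at 1.92. Its lists moved by a median of 1.64 (bulge) and 0.96 (matrix), which held with an estimated correlation. Other medians were -1.13 (sebaceous, adjusted p = 0.102 with an estimated correlation), -0.995 (DNA replication, 0.117), -1.56 (mitosis, 0.116), 0.64 (Hedgehog, 0.0728), 0.73 (BMP and TGF-beta, 0.116), 0.63 (FGF and MAPK, 0.116), -0.49 (cholesterol, 0.311) and -0.68 (interferon, 0.116). With the mouse as a block and cameraPR, the Wnt list (median 0.21, camera adjusted p = 0.141) joined these at 0.00195, beside 506 genes. For the bulge effect, lists called for a difference between the ages, none of them with an estimated correlation, had medians of 0.63 (bulge, adjusted p = 0.319 with an estimated correlation), -0.40 (basal epidermis, 0.0521), -0.60 (epidermal differentiation, 0.534), 0.52 (mitosis, 0.534), 0.46 (Hedgehog, 0.113), -0.53 (immediate early, 0.127), -0.40 (ribosome biogenesis, 0.113) and -0.27 (glycolysis, 0.478).

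Divided bulge cells at PD21 lay close to non-bulge cells, and a mixture with a non-bulge share of 93.5, 93 and 81% in mice 1 to 3 left 0% of 578 genes deviating. That fits, but the test is weak, since forced shares of 75 and 90% also left 0 genes. A share of 100% left 16 (2.77%, within the 5% bound) and 50% left 212, and a state intermediate in each gene would give the same. Bulge-high and non-bulge-high genes alone gave shares of 93.5 and 86.5% in mouse 1 and 93 and 81.5% in mouse 2. In mouse 3 the shares were 80.5 and 82.5%. At an unadjusted p under 0.05 in limma, 45 of the 578 genes deviated from the mixture (lowest adjusted p = 0.112). Swapped divided and non-bulge labels were excluded by the Cd34 gap of 2.55 between their nearest arrays. The array run was tested by 803 genes between divided and undivided bulge within run A, which does not measure closeness to non-bulge cells. On a scale set at PD25, from 0 for undivided bulge to 1 for non-bulge, the divided arrays of run A stood at 0.838 and 0.888. The divided array of run B stood at 0.669, so the closeness was seen in both runs. As a hypothesis, cells that divide before PD21 might lose part of the bulge programme. Staining sorted divided cells for LHX2 and SOX9 would separate the hypotheses, since a mixture predicts 2 classes of cells and a state predicts 1 class of intermediate level.

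Over 61 cell cycle genes the median difference of divided from undivided bulge at PD25 was -0.61 (-1.13, 0.06 and -0.75 per mouse), but 0 passed in limma (635 of all genes at an unadjusted p under 0.05) and the list calls were lost with an estimated correlation (adjusted p = 0.128 for DNA replication and 0.609 for mitosis). Mitosis was also lost by cameraPR without divided mouse 1 (adjusted p = 0.0568), whose array had the highest Gapdh 3' to 5' ratio (11.6) and the lowest weight (0.527). The array run (a size of at least 0.338 in each run, with mouse 1 alone in run A) and a single array (-0.339 left without divided mouse 1) stay open, since the mice left, 2 and 3, differ in sign. Swapped fractions in a mouse cannot be told, as Cd34 differed by -0.333 and no H2B-GFP value was used here. A candidate explanation, untested here, is that undivided cells at PD25 were entering the cycle, which counting EdU in GFP-high and GFP-low bulge cells at PD25 would test.

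Age could not be separated from sex, which also holds for the differences of the division effect and of the bulge effect between the ages. The smallest gap of a Y-linked gene between PD25 and PD21 arrays was 2.91, which fits mice of different sex, and the gap of Xist was 6.27, so sex cannot be told apart from age for the cell cycle genes of undivided cells either. The higher mitosis genes at PD25 may reflect age, sex or both. Both sexes at both ages would be needed to separate them.

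Other splits of the same arrays gave as many genes as the real one in 4 of 84 for bulge against non-bulge at PD21 (489, highest other 1549, in which the undivided arrays stood apart) and 1 of 84 at PD25 (1424, highest other 514). The splits were too few, 1 of 10 reaching the real value, for division at PD21 (958, highest other 0), and for age in undivided (11, 0), divided (907, 0) and non-bulge cells (5, 0). The same held for undivided (1278, 2) and divided (21, 0) against non-bulge at PD21 and undivided (1220, 0) and divided (1026, 0) at PD25. For the difference of the division effect 13 of 100 splits, the real one among them, reached 137 (highest other 577). By the bound set in advance, that share does not exclude chance. The other 12 all left the PD21 arrays in place and so kept the PD21 difference. The 86 that moved PD21 arrays broke up that difference, and 0 of them reached 137 (highest 1). Both outcomes follow from the PD21 difference alone, so the splits cannot decide whether the division effect differs between the ages. Splits say nothing where the real count is 0, as every split reaches it, which was so for division at PD25 (10 of 10, highest other 0) and for the difference of the bulge effect (100 of 100, highest other 1028).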

How the results depend on the processing

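Fits within a run, without an array or with only the groups compared used fewer arrays, and for the other alternatives the cause was not tested. Bulge against non-bulge at PD21 (489 genes) gave 830 with the mouse as a block, 118 within run B and 240 to 456 without 1 array, and at PD25 (1424) 691 within run A. Division at PD21 (958) gave 1533 with the block and 94 within run B. Division at PD25 (0 in limma, 635 at an unadjusted p under 0.05) gave 2 with pseudocount 1, 2 with the stricter filter, 1 without the trend, and 16 with array weights. It gave 10 with the mouse block, 4 with the run block, 23 within run A and 0 to 6 without 1 array. Age in undivided bulge (11) gave 17 with quantile normalisation, 17 with the stricter filter, 5 without the trend and 80 with weights. It gave 22 with the random mouse block, 41 with the run block, 34 within run A, 6 within run B, 40 with only the groups compared and 6 to 25 without 1 array. Age in divided bulge (907) gave 595 within run A, 59 within run B and 525 to 929 without 1 array. The difference of the division effect (137) gave 90 with pseudocount 1, 245 with pseudocount 64, 246 with quantile normalisation, 81 without the trend and 324 with weights. It gave 506 with the mouse block, 392 with the run block, 56 within run A, 0 within run B and 69 to 251 without 1 array. The difference of the bulge effect (0 in limma, 757 at an unadjusted p under 0.05) gave 10 with quantile normalisation, 17 with weights, 30 with the mouse block, 14 with the run block, 8 within run A and 0 to 7 without 1 array. Undivided bulge against non-bulge at PD21 (1278) gave 1926 with the mouse block and 409 within run B, and at PD25 (1220) 1922 with weights and 640 within run A. Divided bulge against non-bulge at PD21 (21) gave 4 without the trend, 49 with the mouse block, 7 within run A, 12 within run B, 1 with only the groups compared and 4 to 30 without 1 array, and at PD25 (1026) 413 within run A. Epidermal differentiation between ages in non-bulge cells reversed from a median of -0.09 (camera adjusted p = 0.823) to 0.227 with the run block (cameraPR adjusted p = 0.0392). In the planned comparisons the mouse block with cameraPR changed no list call beyond those printed. Of the 67 list and comparison pairs called there by camera, fry called 46. These were 6 of 6 and 9 of 9 for the bulge at PD21 and PD25, and 8 of 8 and 0 of 4 for division. For age they were 7 of 13 in undivided, 5 of 6 in divided and 1 of 3 in non-bulge cells. The difference of the division effect had 9 of 10, and that of the bulge effect 1 of 8.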

Other observations

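Some genes of lists that were not called at PD25 still passed between bulge and non-bulge cells. Of 13 Notch pathway genes 4 were higher and 1 lower (adjusted p = 0.289 for the list), with the effector Hey1 at 2.69, the glycosyltransferase Lfng at 1.61 and Rbpj at 1.20. In divided mouse 1, however, Hey1 stood at 4.498 on the log2 scale, within the non-bulge range of 4.138 to 5.498. Of 13 hair germ and early matrix genes 3 were higher and 2 lower (adjusted p = 0.964), with the homeobox genes Hoxc13 at 3.65 and Dlx3 at 3.13, Lef1 at 2.32 and Wnt10a at -1.99. The hypoxia response genes Adm and Egln3 were lower, at -3.45 and -2.43, and the hexokinase Hk2 was higher by 1.62. In divided mouse 1 Adm (12.424) and Hk2 (9.558) stood within the non-bulge ranges of 11.756 to 12.747 and 8.695 to 9.621. Markers of other cells also moved, with the keratin Krt8 higher by 2.42, and the myelin gene Mbp lower at -2.29. Dermal fibroblast genes moved both ways, with the collagens Col1a1 and Col6a1 higher by 2.77 and 2.58 and the surface gene Thy1 lower at -1.49.

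A scale ran from 0 for undivided bulge to 1 for non-bulge, with the genes and both end points taken from the other age. On it, divided bulge averaged 0.798 (SD 0.115, n = 3) at PD21 and 0.136 (SD 0.061) at PD25. Undivided bulge and non-bulge averaged 0.095 and 1.001 at PD21, and 0.029 and 0.915 at PD25, so offsets between the ages enter these values. Undivided bulge against non-bulge had a correlation across genes of 0.773 between the ages, which share no arrays, with 482 genes higher at both ages (40.5 by chance), 351 lower at both (27.5 by chance) and 0 opposite. With the mouse as a block and cameraPR, lists for the difference of the bulge effect gained a call for isthmus (median -0.44, adjusted p = 0.0234), replication (0.24, 0.0196), matrix (0.29, 0.0173), oxidative phosphorylation (-0.16, 0.00586) and interferon genes (-0.42, 0.0241), beside 30 genes.

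Without a block, the lists not called in any planned comparison were those of Merkel and nerve, Notch, endothelial, erythroid, hair germ, hair shaft, immune, melanocyte and oxidative phosphorylation genes. Their smallest camera adjusted p was 0.0503, for melanocyte genes between ages in non-bulge cells (median -0.65). Only 1 erythroid, 2 endothelial, 3 Merkel and nerve and 4 melanocyte genes were tested, so the lack of a call says little about those cells.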
